A study of Mus musculus with 12 samples.

How the data were processed

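RNA sequencing of mouse skin was examined in 12 libraries, each from total RNA of a biopsy. Per the labels, RNA was isolated with a Qiagen RNeasy kit, libraries followed a standard Illumina protocol, and reads were processed with STAR and Partek 8.0.19 against GRCm38.p6. The annotation used by the authors and the program that counted reads are not given in the sources used here, and neither are the strain and sex of the mice or the tick species. The deposited table gives CPM, the reads of a gene per M (mega) reads of its library, for 25070 named genes, to which the authors had added 0.0001 in every cell. That offset was subtracted only for the estimate of depth and was left in all other values. With it the columns summed to between 998572 and 998966 CPM. Of the gene names, 25 had been turned into dates and 2 occurred more than once.

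No count table was used here, so depth was estimated from the deposited CPM. Values between 0.01 and 3 CPM fell on whole multiples of 1 step in each library, within 0.02 reads, for 73.6% to 79.4% of the values, against at most 36% for any unrelated step. The step was taken as the CPM of 1 read. It gave between 12.5 M and 29.8 M reads per library. As whole reads could not be recovered for every value, the planned count tests were not run. A level of 3 reads was used as the detection floor, which lay between 0.101 and 0.24 CPM. It covers counting error only.

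Libraries were grouped by their labels into unbitten naive skin (n = 2), first exposure (n = 3), ticks 2x (n = 3), ticks 3x (n = 3) and saliva immune (n = 1). The saliva immune library was left out of every fit, since a single library gives no test, and was described only. The labels carry no pairing of the samples and do not say whether each library came from a separate animal. No paired analysis was possible because no replicate number links the groups.

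Genes were compared with limma 3.58.1 in R 4.3.3, on log2(CPM + 1), with a trend in the prior variance, for genes with at least 1 CPM in at least 2 of the 11 libraries in the fit. That left 17064 genes. A fit with 4 groups (7 residual degrees of freedom) gave 7 of the 8 comparisons. Repeat exposure, meaning 2x and 3x pooled (n = 6), was compared with first exposure in a fit with 3 groups (8 residual degrees of freedom). Calls required a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, with no fold threshold. Standard errors (SE) of log2 fold changes are limma's. Levels are means ± SD in CPM.

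Gene lists for skin, immune and stromal cell types, cytokine programmes and tissue composition were fixed beforehand: 49 lists with 779 genes, of which 739 were found by symbol, 1 by a synonym (Il36g, named Il1f9 in the table) and 39 not at all. The 47 lists with at least 3 tested genes were tested with limma's camera at its preset correlation between genes of 0.01, with adjustment over the lists within a comparison. The same test was repeated with the correlation estimated from the data, whose median over lists was 0.507. Members of a list were counted as past the threshold over all genes, and again adjusted over the list alone. Of the symbols in the table, 22654 (90.5%) were found in the RefSeq annotation of GRCm38.p6, which gave the coordinates.

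Genes were named by a rule. It took the 10 largest rises and the 10 largest falls among called genes whose libraries did not overlap between the sides and whose mean was at least 5 CPM on the higher side, and it left out predicted or clone-named genes and receptor or antibody segments. For each list described it added up to 4 called members, or the 2 members with the highest mean CPM where none was called. Il4, Il13, Ifng, Il17a, Il10, Mcpt8, Cd4, Cd207 and Krt6a were always to be named. Il17a was not used here, and Il13 and Ifng did not reach the minimum level for testing.

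The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were other pseudocounts (0.5 and 0.1), no filter or a filter at 5 CPM, median-of-ratios scaling, quantile normalization, totals without the top 50 genes, fits with only the groups compared, robust variance moderation, array weights, a minimum absolute log2 fold change of 1, camera with an estimated correlation, and leaving out each library in turn. Alternatives added after the data were seen were a covariate for the mean of the hair follicle list and voom weights on the estimated reads. Of the 11 libraries in the fit, other splits into groups of the same sizes were also counted. The test was checked on simulated data with known changes of 1, 2 and 4 on the log2 scale. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.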

Results

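Gene expression was measured by RNA sequencing in skin from mice infested with ticks, in biopsies taken 4 days after attachment. The series asks how the skin of mice responds to repeated infestation. Skin was sampled without a bite (naive, n = 2), after a first exposure (n = 3), and from mice labelled ticks 2x (n = 3) and ticks 3x (n = 3). A single library came from a bitten mouse labelled saliva immune (n = 1). The labels do not say whether the sampled infestation is included in 2x and 3x, or how saliva immunity was raised. Estimated depth was 29.8 M and 12.5 M reads for the naive libraries, 28.6 M, 17.9 M and 23.2 M for first exposure, 20.3 M, 18.9 M and 16.1 M for 2x, 20.5 M, 21.4 M and 20.1 M for 3x, and 25.6 M for saliva immune. The 50 genes with the highest levels held between 17.2% and 25.4% of each library.

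The libraries differed in tissue composition inside every group. The mean of the hair follicle list, which holds hair keratins and follicle regulators, was 7.55 and 0.85 on the log2(CPM + 1) scale in the naive libraries. It was 9.14, 9.44 and 1.47 after first exposure, 8.96, 2.54 and 0.71 in 2x, and 5.02, 6.67 and 0.78 in 3x. The first principal component held 53% of the variance, and the 3 libraries with the highest hair follicle means had the 3 lowest scores on it. Across genes, which are not independent replicates, pairs of libraries of 1 group correlated with a median of 0.945 (10 pairs) and pairs from different groups with a median of 0.949 (56 pairs). The sample titles put the first exposure and saliva immune libraries in 1 numbered series and the other 8 libraries in another. Comparisons with first exposure therefore cannot separate exposure from title series, and no value within a series can be given for them.

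**Figure D1:**
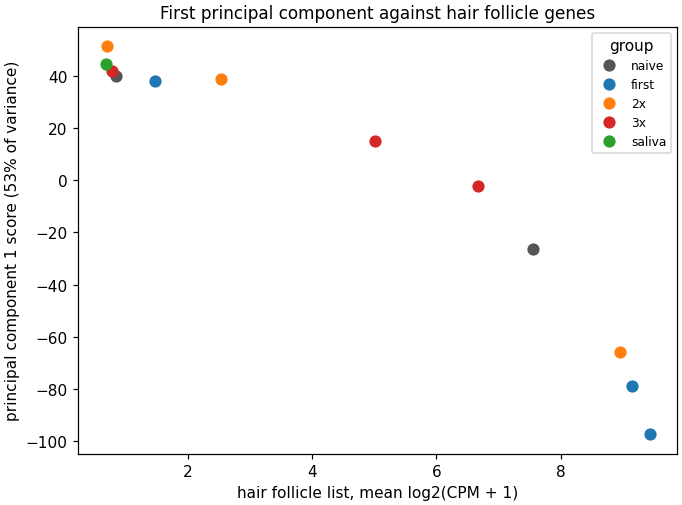
Score on the first principal component (vertical axis, 53% of the variance) against the mean of the hair follicle list in log2(CPM + 1) (horizontal axis), where each point is 1 of the 12 libraries and its colour is the group. The 3 libraries with means of 8.96, 9.14 and 9.44 have the lowest scores.

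First exposure was compared with naive skin to show what a first bite changed. Oxtr, the oxytocin receptor (chromosome 6, 112473683 to 112491035), fell from 90.7 ± 13.1 CPM in naive skin (SD, n = 2) to 6.08 ± 0.549 CPM after first exposure (SD, n = 3). Rps12, a protein of the small ribosomal subunit (chromosome 10, 23785183 to 23787383), rose from 39.5 ± 6.4 CPM to 105 ± 3.29 CPM. It was also among the 98 genes that limma called lower after repeat than after first exposure (log2 fold change -0.78, adjusted p = 0.0249). In the saliva immune library, of the first exposure title series, it was at 128 CPM, so a bite and title series cannot be told apart here. All 19 tested adipocyte genes lay lower after first exposure, with a median log2 fold change of -1.17 (camera adjusted p = 1.43e-15; adjusted p = 0.739 with an estimated correlation). None of them passed over all genes, and 16 passed as lower when adjusted over the list alone. Car3, the carbonic anhydrase of fat and muscle, was at 3523 ± 74.1 CPM in naive skin and 1325 ± 251 CPM after first exposure (adjusted p = 0.16).

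Several other gene groups lay apart between these sides, and none of their members was called over all genes. Immediate early genes, which are switched on within minutes of stimulation, had a median of -1.93, with 11 of 17 lower and 1 higher when adjusted over the list alone (camera adjusted p = 3.44e-06; adjusted p = 0.739 with an estimated correlation). Their list means were 8.21 and 9.13 in the naive libraries, 6.28 and 5.83 in first exposure replicates 1 and 2, which hold much hair follicle, and 8.02 in replicate 3, which holds little. However, 2x replicate 1, with a hair follicle mean of 8.96, was at 8.12, and the saliva immune library, with one of 0.68, was at 6.86. The latter, of the first exposure title series, lay below all 8 libraries of the other series, the lowest of which was at 7.8. First exposure and title series therefore cannot be told apart for this list. Fos was at 2451 ± 1319 CPM in naive skin and 385 ± 581 CPM after first exposure, with 76, 23.4 and 1055 CPM in its 3 libraries (log2 fold change -4.17, adjusted p = 0.163). Lymphatic genes had a median of -1.47, with 5 of 7 lower adjusted over the list alone (4.22e-05; adjusted p = 0.739 with an estimated correlation). Lyve1, the hyaluronan receptor of lymphatic vessels, was at 81.4 ± 44.7 CPM in naive skin and 18.7 ± 1.28 CPM after first exposure. All 14 endothelial genes lay lower (median -0.90, 1.94e-05; adjusted p = 0.739 with an estimated correlation). All 21 cell cycle genes lay higher (median 0.88, 1.03e-05; adjusted p = 0.739 with an estimated correlation), and Mki67, a marker of dividing cells, was at 108 ± 23.3 CPM against 219 ± 84 CPM (adjusted p = 0.427). Cell cycle means were 4.4 and 3.9 in the naive libraries, 5.29 and 5.33 in first exposure replicates 1 and 2 and 4.48 in replicate 3, and the median was 0.58 with the hair follicle mean as a covariate. In this comparison the hair follicle list had a median of 2.58 (camera adjusted p = 0.135) and the melanocyte list one of 2.18 (0.134), and on leaving out 1 library the first lay between -1.1 and 6.25 and the second between 0.98 and 4.09.

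Of 17064 genes, limma called 1 higher and 1 lower, while 2798 had an unadjusted p under 0.05 and 853 would by chance. The log2 fold change was -3.69 for Oxtr (SE 0.32, adjusted p = 0.0144) and 1.40 for Rps12 (SE 0.14, adjusted p = 0.0214), and the libraries of the 2 sides did not overlap for either gene. Camera called 1 list higher and 18 lower, and 0 with an estimated correlation. The Oxtr call was lost without naive replicate 1 (adjusted p = 0.0898), naive replicate 2 (0.124), first exposure replicate 1 (0.0584) or first exposure replicate 2 (0.0594), while its fold change stayed between -3.84 and -3.54. The Rps12 call was lost without naive replicate 1 (0.0747), naive replicate 2 (0.149), first exposure replicate 1 (0.0944) or first exposure replicate 2 (0.115). It was also lost in a fit with only the naive and first exposure libraries (0.273), which called 0 genes higher and 2 lower, Oxtr among them. Without first exposure replicate 3, 600 genes were called.

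Skin labelled 2x was compared with naive skin within 1 title series. Camera called 10 lists higher and 6 lower in 2x, and 0 with an estimated correlation. No member of the mast cell, basophil, macrophage and chemokine lists was called over all genes. Of 17 mast cell genes, 16 lay higher (median log2 fold change 0.96, camera adjusted p = 0.000452; adjusted p = 0.921 with an estimated correlation). Mcpt4, the chymase of connective tissue mast cells, was at 66.9 ± 9.28 CPM in naive skin (n = 2) and 131 ± 2.04 CPM in 2x (n = 3), and Cpa3, a mast cell carboxypeptidase, at 51.2 ± 8.47 and 124 ± 18 CPM. Of 16 basophil genes, 15 lay higher (median 1.06, camera adjusted p = 0.000642; adjusted p = 0.921 with an estimated correlation). Mcpt8, the basophil protease, was listed at 0 in both naive libraries, where 3 reads would be 0.101 and 0.24 CPM, and was at 0.049, 6.18 and 5.15 CPM in the 2x libraries (adjusted p = 0.53).

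Of 10 monocyte chemokine genes, 9 lay higher in 2x than in naive skin, with a median of 1.67 (camera adjusted p = 0.00384; adjusted p = 0.921 with an estimated correlation). Ccl8, a chemokine that attracts monocytes and eosinophils, was at 45.6 ± 22.2 CPM in naive skin and 634 ± 419 CPM in 2x (log2 fold change 3.52, SE 1.14, adjusted p = 0.342), and Ccl6 at 140 ± 89.5 and 509 ± 223 CPM. Of 20 macrophage genes, 19 lay higher (median 0.91, 0.000452; adjusted p = 0.921 with an estimated correlation), and all 12 neutrophil-recruiting cytokines did (median 1.62, 0.000729; adjusted p = 0.921 with an estimated correlation). The last call was lost without naive replicate 1 (adjusted p = 0.0664) or 2x replicate 2 (0.118, median 0.67), and its median was 2.59 without 2x replicate 1. The macrophage median was 0.46 without naive replicate 2 and 0.54 without 2x replicate 2. Skeletal muscle genes were lower (median -1.84, 23 of 26 below 0, 2e-05; adjusted p = 0.921 with an estimated correlation), with list means of 8.8 and 8.28 in the naive and 5.76, 5.88 and 9.13 in the 2x libraries, and a median of -1.18 without 2x replicate 1 and -2.98 without 2x replicate 3.

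At single genes, Pgr, the progesterone receptor (chromosome 9, 8898900 to 8968611), fell from 33.7 ± 12.3 to 0.315 ± 0.178 CPM between naive and 2x skin (log2 fold change -4.69, SE 0.56, adjusted p = 0.0447). Oxtr fell to 7.15 ± 2.05 CPM (-3.52, SE 0.32, adjusted p = 0.0202). Enpep, the aminopeptidase that cleaves angiotensin II (chromosome 3, 129269177 to 129332749), fell from 73.6 ± 2.83 to 23.3 ± 3.55 CPM (adjusted p = 0.045). The membrane protein gene Tmem132c (chromosome 5, 127241826 to 127565790) fell from 19.3 ± 1.56 to 5.75 ± 0.565 CPM (adjusted p = 0.0397), and Pcdh18, a protocadherin of cell adhesion (chromosome 3, 49743291 to 49757383), from 23.6 ± 0.621 to 8.41 ± 0.348 CPM (adjusted p = 0.0202). The sixth call was Gpr165, an orphan receptor under 5 CPM that was added after its values were seen (log2 fold change -1.52, SE 0.169, adjusted p = 0.0396). Its call was lost without any 2x library (0.0877, 0.165 and 0.123 for replicates 1, 2 and 3). For all 6 genes the naive and 2x libraries did not overlap.

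limma called 0 genes higher and 6 lower in 2x, with 1867 at an unadjusted p under 0.05 and 5 called by voom. A fit with only the naive and 2x libraries called 0 genes, as did every fit without 1 library but that without 2x replicate 1. The latter called 3 genes higher and 2 lower, and the 2 lower, Oxtr and Pcdh18, were among the 6. Without naive replicate 1 the adjusted p was 0.38 for Oxtr and 0.48 for Pgr, Enpep, Tmem132c and Pcdh18, without naive replicate 2 it lay between 0.119 (Oxtr) and 0.433 (Enpep), without 2x replicate 1 between 0.0422 (Oxtr) and 0.13 (Enpep), without 2x replicate 2 between 0.0908 (Oxtr) and 0.215 (Enpep), and without 2x replicate 3 between 0.0759 (Oxtr) and 0.168 (Pgr).

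Skin labelled 3x was compared with naive skin within the same title series. Nnat, the imprinted gene for neuronatin (chromosome 2, 157560078 to 157562525), rose from 5.68 ± 1 CPM in naive skin (SD, n = 2) to 51.8 ± 9.05 CPM in 3x (SD, n = 3). All 16 basophil genes lay higher (median log2 fold change 0.72, camera adjusted p = 0.00143), as did 15 of 17 mast cell genes (median 1.03, 0.000281) and 17 of 18 T cell genes (median 0.72, 0.000557). With an estimated correlation each adjusted p was 0.98. Erythrocyte genes, which mark blood, lay higher as well in 8 of 8 (median 1.10, 0.00664; adjusted p = 0.98 with an estimated correlation), with list means of 3.89 and 3.83 in the naive and 4.61, 4.93 and 4.98 in the 3x libraries, and the call was lost without naive replicate 1 (0.0904) or 3x replicate 3 (0.144). All 26 skeletal muscle genes lay lower (median -0.93, 0.00114; adjusted p = 0.98 with an estimated correlation), with list means of 6.52, 7.21 and 9.22 in the 3x libraries. This call was lost without 3x replicate 1 (0.28, median -0.38) or 3x replicate 2 (0.0607). The muscle median was -1.87 without 3x replicate 3 and -0.43 without naive replicate 1. Mcpt4 was at 130 ± 55.7 CPM (adjusted p = 0.825), and Mcpt8 was at 6.91 and 7.57 CPM in 2 libraries and listed at 0 in 3x replicate 3 (adjusted p = 0.766). Cd4, the coreceptor of helper T cells, was at 1.3 ± 0.417 CPM in naive skin and 5.6 ± 4.46 CPM in 3x, and Il4, the type 2 cytokine, at 0.401 ± 0.003 and 1.5 ± 1.4 CPM (adjusted p = 0.842). Type I interferon response genes, which are induced by viral or nucleic acid sensing, were lower, with 20 of 22 below 0 (median -0.51, 2.15e-05; adjusted p = 0.98 with an estimated correlation). Much of this came from 3x replicate 3, whose list mean was 3 against 3.8 and 4 in the other 3x libraries and 4.17 and 3.94 in naive skin: without it the median was -0.23 (adjusted p = 0.0129), while that of the basophil list was 1.35.

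limma called 1 gene higher and 0 lower in 3x, with 1186 at an unadjusted p under 0.05, and voom called 0. The log2 fold change of Nnat was 2.98 (SE 0.29, adjusted p = 0.0348) without overlap of the libraries. Its call was lost in a fit with only the naive and 3x libraries (0.142), and without naive replicate 1 (0.987), naive replicate 2 (0.192), 3x replicate 1 (0.201), 3x replicate 2 (0.256) or 3x replicate 3 (0.0862). Camera called 8 lists higher and 6 lower, and 0 with an estimated correlation. The 2 comparisons with naive skin shared 0 called genes: all 6 genes lower in 2x had the same sign in 3x, with adjusted p between 0.106 and 0.509. Both used the same naive libraries. The covariance of their fold changes across genes was 0.16, against a mean of 0.127 and a highest value of 0.145 in 100 simulations of groups without a change. The simulated genes varied independently, while the estimated correlation between genes of a list had a median of 0.507. The simulations therefore cannot say whether 2x and 3x share a response.

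The 3 bitten groups together were compared with naive skin, to find what any bite changed. Oxtr fell from 90.7 ± 13.1 CPM (n = 2) to 9.45 ± 5.21 CPM in bitten skin (n = 9). Enpep, Tmem132c and Pcdh18 fell as well, by 1.53, 1.25 and 1.12 on the log2 scale. All 19 adipocyte genes lay lower in bitten skin (median log2 fold change -0.70, camera adjusted p = 1.2e-08; adjusted p = 0.9 with an estimated correlation), and 4 of them passed adjusted over the list alone. By group, their median against naive skin was -1.17 for first exposure, which is in the other title series, -0.62 for 2x and -0.18 for 3x. The list mean of 3x replicate 3 (8.13) lay above both naive libraries (7.72 and 8.03). The pooled fall thus cannot be separated from title series. Interferon response genes were lower (median -0.50, 21 of 22 below 0, 3.74e-06), and so were lymphatic genes (median -1.05, 0.000554; -0.41 without naive replicate 2) and skeletal muscle genes (median -0.997, 0.000554). With an estimated correlation each adjusted p was 0.9. The mast cell list was the only one of 47 called higher (median 0.52, 15 of 17 above 0, 0.0262; adjusted p = 0.9 with an estimated correlation), and its call was lost without naive replicate 1 (adjusted p = 0.124).

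limma called 0 genes higher and 7 lower in bitten skin, with 1903 at an unadjusted p under 0.05 and 9 called by voom. The log2 fold change of Oxtr was -3.26 (SE 0.28, adjusted p = 0.011), and its adjusted p was 0.304 without naive replicate 1, 0.165 without naive replicate 2 and 0.0524 without first exposure replicate 1. Enpep (0.0415), Tmem132c (0.0448) and Pcdh18 (0.0336) were lost without any 1 library other than first exposure replicate 3 and 3x replicate 3, and Tmem132c without the latter as well, with adjusted p between 0.0618 and 0.408 for Enpep, up to 0.481 for Tmem132c and up to 0.344 for Pcdh18. The count ranged from 0 to 8 on leaving out 1 library, and of the 8, without first exposure replicate 3, 5 were among the 7. The other 3 calls, Gpr165, Shisa6 and the major urinary protein gene Mup13, were under 5 CPM and were added after their values were seen (adjusted p = 0.0448 each). Without 1 bitten library Shisa6 was lost in every case (0.0571 to 0.144). Gpr165 was lost in all but that without first exposure replicate 3 (0.0459) and Mup13 in all but that without 3x replicate 3 (0.0372). Without a naive library these 3 genes were not tested. Of the genes always named, Il4 had a log2 fold change of 0.19, Il10 of -0.89, Mcpt8 of 1.33, Cd4 of 0.73, Cd207 of -0.30 and Krt6a of 0.68, with adjusted p between 0.613 and 0.903. On leaving out 1 library, Il4 lay between 0.15 and 0.37, Il10 between -1.29 and -0.49, Cd4 between 0.48 and 0.97 and Cd207 between -0.71 and 0.12.

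**Figure D2:**
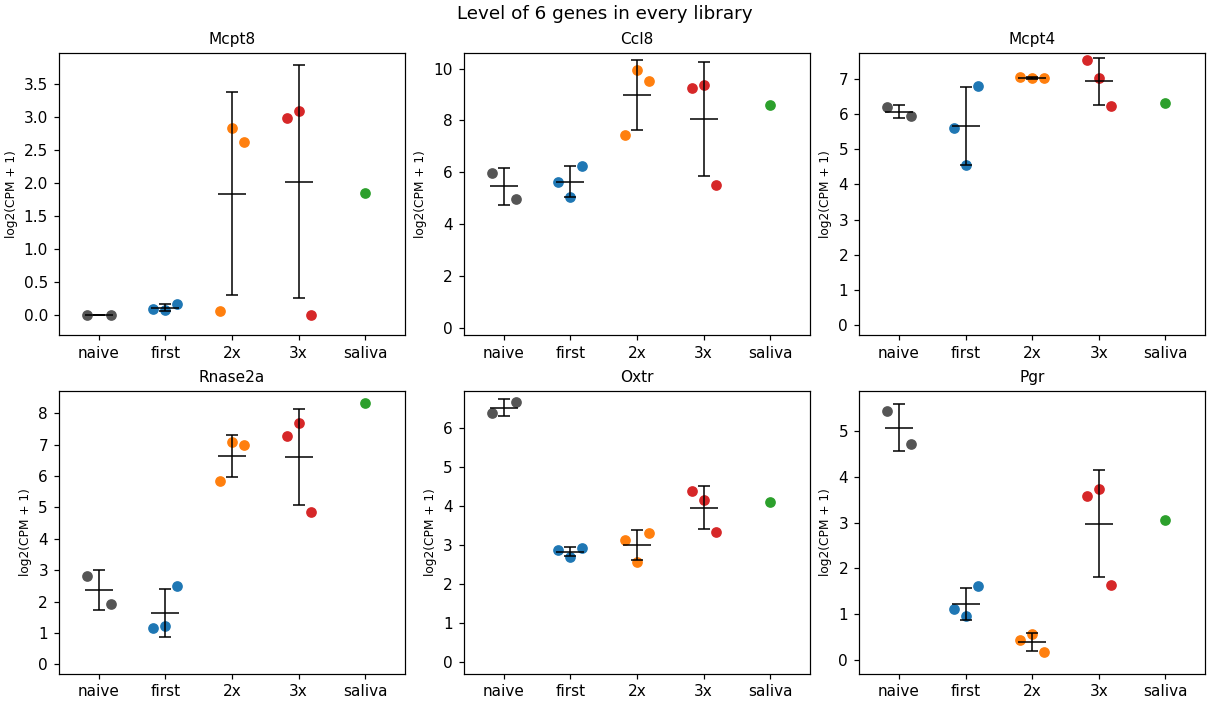
Levels of 6 genes as log2(CPM + 1) (vertical axes, 1 panel per gene) by group (horizontal axes). Points are libraries, lines are means and bars are the SD on that scale, and the single saliva immune library has neither. Before the log, Oxtr was at 81.4 and 99.9 CPM in the naive libraries and at most at 19.8 CPM in the bitten ones.

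Repeat exposure, 2x and 3x pooled, was compared with first exposure to show what earlier infestations added. Rnase2a, a member of the eosinophil-associated ribonuclease family (chromosome 14, 51255261 to 51256112), rose from 2.41 ± 1.95 CPM after first exposure (SD, n = 3) to 117 ± 65.1 CPM after repeat exposure (SD, n = 6), against 4.4 ± 2.27 CPM in naive skin. Genes of fat were higher as a group: 18 of 19 adipocyte genes lay above first exposure (median log2 fold change 1.00, camera adjusted p = 2.4e-11; adjusted p = 0.271 with an estimated correlation), 2 were called over all genes and 14 passed adjusted over the list alone. Adipoq, the hormone adiponectin (chromosome 16, 23146536 to 23157968), rose from 116 ± 39.4 to 340 ± 107 CPM, and Cidec, a lipid droplet protein, from 120 ± 49 to 341 ± 86 CPM. In naive skin they were at 327 ± 49.3 and 249 ± 63.4 CPM. In the sebaceous gland list 1 of 18 genes was called, the duct keratin Krt79, which rose from 107 ± 29.8 to 270 ± 64.1 CPM (list median 0.73, 4.62e-06; adjusted p = 0.271 with an estimated correlation). The list median was 0.48 without first exposure replicate 2 and 1.10 without first exposure replicate 3.

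Camera called 34 of 47 lists higher after repeat exposure and 4 lower, and 0 with an estimated correlation. All 16 basophil genes lay higher (median 1.19, camera adjusted p = 7.27e-08; adjusted p = 0.271 with an estimated correlation), and 11 passed adjusted over the list alone. Csf2rb, the receptor chain shared by IL-3, IL-5 and GM-CSF, was at 29 ± 17.3 CPM after first exposure, 107 ± 78.2 CPM in 2x and 92 ± 60.7 CPM in 3x (adjusted p = 0.196 for repeat exposure), and Mcpt8 was at 0.085 ± 0.039 CPM, under the floor of 3 reads, and 4.31 ± 3.42 CPM (adjusted p = 0.206). Basophil list means were 1.88, 1.43 and 2.55 after first exposure, 2.64, 4.25 and 3.76 in 2x, and 3.81, 3.98 and 2.16 in 3x. Of 17 mast cell genes, 14 lay higher (median 1.19, 4.07e-06; adjusted p = 0.271 with an estimated correlation), with 11 higher and 1 lower adjusted over the list alone, and a median of 0.67 without first exposure replicate 2. Monocyte chemokines had a median of 2.36 (2.08e-06, 8 of 10 higher adjusted over the list alone; adjusted p = 0.271 with an estimated correlation), with Ccl8 at 51.2 ± 21.3 and 537 ± 359 CPM (adjusted p = 0.129). All 15 genes of alternatively activated macrophages lay higher (median 1.42, 2.46e-08, 7 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation), and Mrc1, the mannose receptor, was at 144 ± 92.1 and 504 ± 306 CPM. Against naive skin the median of this macrophage list was -0.91 after first exposure, 0.48 in 2x and 0.17 in 3x. No member of these 4 lists was called over all genes. Cd163, the scavenger receptor for haemoglobin, which belongs to the general macrophage list, was at 93.9 ± 56.2 and 644 ± 432 CPM.

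Lists outside the immune cells lay apart as well. The median was 1.76 for immediate early genes (camera adjusted p = 5.92e-07), 1.44 for erythrocyte genes (0.00148) and 0.82 for lymphatic genes (0.00398), each with an adjusted p of 0.271 with an estimated correlation. It was 0.88 for endothelial genes (2.99e-05; adjusted p = 0.325 with an estimated correlation), 0.75 for epidermal differentiation (0.00137; adjusted p = 0.457 with an estimated correlation), -1.07 for skeletal muscle (0.00836; adjusted p = 0.61 with an estimated correlation) and -2.46 for melanocytes (0.0132; adjusted p = 0.457 with an estimated correlation). For immediate early genes the saliva immune library, of the first exposure title series, had a list mean of 6.86, against 7.8 to 8.83 in the 2x and 3x libraries. Without first exposure replicate 2 the erythrocyte median was 0.82 and the epidermal one 0.24 (0.0503), which was 1.40 without first exposure replicate 3. The muscle call was lost without first exposure replicate 3 (0.215) or 2x replicate 1 (0.0949), and the melanocyte call without first exposure replicate 1 (0.0504) or 2 (0.143, median -1.30), with a median of -4.27 without replicate 3. Inside the first exposure group, replicate 3, which holds little hair follicle, lay above replicates 1 and 2 in several immune lists. Macrophage list means were 5.94 against 4.89 and 4.15, and MHC class II means 5.61 against 4.41 and 3.75. It lay below replicate 1 in the neutrophil (1.72 against 2.06), B and plasma cell (2.26 against 2.49) and antimicrobial peptide (3.28 against 3.45) lists.

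T cell genes lay higher in 18 of 18 (median 0.75, 4.46e-07), genes of the type 2 response in 14 of 16 (median 0.65, 0.000166) and eosinophil genes in 6 of 6 (median 0.80, 0.0017), with 1, 3 and 3 passing adjusted over the list alone. With an estimated correlation the adjusted p was 0.271, 0.3 and 0.271 in that order. The eosinophil median was 0.43 without first exposure replicate 2. Il4ra, the IL-4 receptor chain, was at 64 ± 44.9 and 238 ± 166 CPM. Il4 was at 0.196 ± 0.081 and 1.04 ± 1.04 CPM (adjusted p = 0.33), Il10 at 0.197 ± 0.204 and 4.97 ± 4.18 CPM (0.145) and Cd4 at 0.85 ± 0.63 and 6.13 ± 5.44 CPM (0.184). Cd207, the Langerhans cell lectin, was at 15.8 ± 15.3 and 20 ± 7.06 CPM, and Krt6a, a keratin of wounded epidermis, at 164 ± 109 and 271 ± 168 CPM. Il13 was at 0.099 ± 0.088 and 0.729 ± 0.308 CPM and Ifng at 0.029 ± 0.05 and 0.101 ± 0.105 CPM, and neither was tested. Cell cycle genes were lower in 21 of 21 (median -0.95, 2.12e-07, 14 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation), with Mki67 at 219 ± 84 and 96.9 ± 55.9 CPM. Hair follicle genes were lower in 28 of 28 (median -2.73, 0.00974; adjusted p = 0.632 with an estimated correlation), a call lost without first exposure replicate 1 (0.129), first exposure replicate 2 (0.331) or 2x replicate 3 (0.0618). Its medians were -1.37 and -1.12 in the first 2 cases and -5.61 without first exposure replicate 3.

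limma called 42 genes higher and 98 lower, with 3518 at an unadjusted p under 0.05. By the naming rule, Rnase2a had the largest rise (log2 fold change 4.99, SE 0.59, adjusted p = 0.0249), followed by the Mas-related receptor Mrgprg (2.99), the matrix protein gene Cyr61 (2.54), the lipid hydrolase Ces1d (2.02), Pck1 of gluconeogenesis (2.02), Cyp2e1 (2.00), Dnm3os (1.87), Ces1f (1.77), Rasd1 (1.67) and Pde3b, which restrains lipolysis (1.66). At 36 of the 42 higher genes both naive libraries lay above all first exposure libraries, against 14% of all genes. Cyr61 was at 684 ± 239 CPM in naive skin, 70.8 ± 67.6 CPM after first exposure and 331 ± 117 CPM after repeat exposure. In the same order Ces1d was at 164 ± 47.4, 39.7 ± 13.4 and 164 ± 53.1 CPM, and Rasd1 at 33.6 ± 17.9, 3.36 ± 1.32 and 12.9 ± 3.66 CPM. Mrgprg was at 0.613 ± 0.415, 2.22 ± 2.86 and 20.8 ± 8.96 CPM. At 93 of the 98 lower genes both naive libraries lay below all first exposure libraries, against 21% of all genes. By the naming rule, which leaves out predicted and clone-named genes such as Gm15427 (-2.22), the largest falls were at the pseudogenes Rpl14-ps1 (-2.01), Rpl32p (-1.99), Rps27a-ps2 (-1.77), Rps23-ps2 (-1.68), Rpl31-ps12 (-1.65), Rps2-ps13 (-1.62), Eef1a1-ps1 (-1.55) and Eif4a-ps4 (-1.23), whose reads can be shared with their parent genes, and at the small cytoplasmic RNA Bc1 (-1.63) and Rnaset2b (-1.54). Their adjusted p lay between 0.0249 and 0.0485. Predicted or clone-named genes made up 69 of the 98 lower and 9 of the 42 higher genes. At 92 of the 98 lower genes the saliva immune library, of the first exposure title series, lay above all 8 libraries of the other series, against 12.6% of all genes. The called genes were chosen for their first exposure, 2x and 3x levels, and that choice alone can raise these counts. No gene was called without first exposure replicate 2, 2x replicate 3, 3x replicate 1 or 3x replicate 2, while 51 were called without first exposure replicate 1 (44 of them among the 140), 2260 without first exposure replicate 3 (138), 73 without 2x replicate 1 (60) and 28 without 2x replicate 2 (28). For Rnase2a the adjusted p in the first 4 cases was 0.133, 0.064, 0.0641 and 0.0615.

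**Figure D3:**
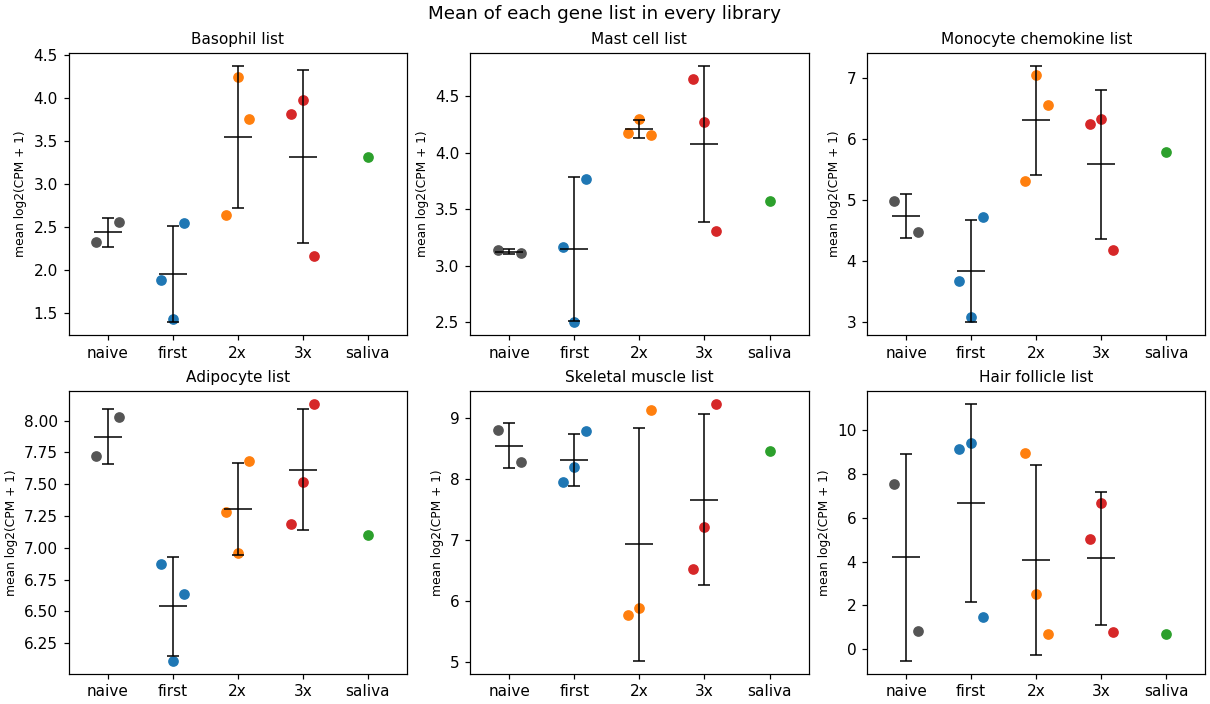
Mean of log2(CPM + 1) over the members of 6 gene lists (vertical axes, 1 panel per list) by group (horizontal axes), where points are libraries, lines are means and bars are the SD, and the single saliva immune library has neither. The basophil mean is 2.16 in 3x replicate 3 and 3.81 and 3.98 in the other 3x libraries.

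Each repeat group was also compared with first exposure on its own. In 2x skin all 16 basophil genes (median log2 fold change 1.24, camera adjusted p = 5.57e-08), all 12 neutrophil-recruiting cytokines (median 3.94, 8.21e-08) and all 10 monocyte chemokines (median 2.75, 1e-07) lay higher, and 6, 7 and 8 of them passed adjusted over the list alone. With an estimated correlation each adjusted p was 0.339. Means of the neutrophil-recruiting list were 2.16, 5.79 and 4.54 in 2x, 0.99, 0.82 and 2.01 after first exposure, and 2.02 and 2.63 in naive skin. In this list 2x replicate 1 thus lay near first exposure replicate 3 and between the naive libraries. In 3x skin all 16 basophil genes lay higher (median 1.18, 6.07e-06; adjusted p = 0.411 with an estimated correlation), none adjusted over the list alone. All 21 cell cycle genes lay lower (median -1.28, 7.61e-12), 20 of them adjusted over the list alone, and all 19 adipocyte genes lay higher (median 1.04, 7.97e-12), 15 adjusted over the list alone. With an estimated correlation each adjusted p was 0.411. Cell cycle means in the 3x libraries were 3.8, 4.31 and 3.2, and the median was -1.01 with the hair follicle mean as a covariate. The hair follicle list had a median of -2.81 in 2x (0.0369; adjusted p = 0.711 with an estimated correlation) and -2.65 in 3x (0.0183; adjusted p = 0.67 with an estimated correlation), and the melanocyte list one of -2.31 in 2x (0.0445; adjusted p = 0.573 with an estimated correlation) and -2.49 in 3x (0.0191; adjusted p = 0.489 with an estimated correlation). All 4 calls were lost without first exposure replicate 1 or 2, with medians between -1.68 and -1.11, and the medians were -5.65, -5.60, -4.11 and -4.43 in that order without first exposure replicate 3. In 2x both calls were also lost without 2x replicate 2 (0.245 for each) or 3 (0.806 for the hair follicle and 0.262 for the melanocyte list), with medians of -5.49 and -3.78 without 2x replicate 1. In 3x the hair follicle call was lost without 3x replicate 3 (0.192, median -0.84). Skeletal muscle genes had a median of -1.58 in 2x (0.00077; adjusted p = 0.564 with an estimated correlation), a call lost without 2x replicate 1 (0.134, median -0.90) or first exposure replicate 3 (0.0774) and with a median of -2.66 without 2x replicate 3. Erythrocyte genes had a median of 1.86 in 3x (0.000428; adjusted p = 0.411 with an estimated correlation), which was 1.21 without first exposure replicate 2. limma called 0 genes in 2x against first exposure and 0 in 3x against first exposure, as did voom, with 2710 and 3035 at an unadjusted p under 0.05 and smallest adjusted p of 0.0822 and 0.082. Without first exposure replicate 3 the counts were 137 and 1372, without 2x replicate 1 the first was 2, and without first exposure replicate 1 and 3x replicate 3 the second was 5 and 1.

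Skin labelled 3x was compared with 2x within 1 title series, to show what a further exposure level changed. All 21 cell cycle genes lay lower in 3x (median log2 fold change -0.64, camera adjusted p = 3.6e-11; adjusted p = 0.991 with an estimated correlation). Mki67 was at 124 ± 65.7 CPM in 2x (n = 3) and 70.1 ± 36.5 CPM in 3x (n = 3), and Top2a, a topoisomerase of dividing cells, at 71.7 ± 25.8 and 49.4 ± 19.7 CPM (adjusted p = 0.894 for each). Neutrophil-recruiting cytokines were lower in 9 of 12 (median -1.59, 0.00609; adjusted p = 0.991 with an estimated correlation), and Il1b, the inflammatory cytokine, was at 157 ± 158 and 28.2 ± 22.6 CPM (adjusted p = 0.894). Monocyte chemokines were lower in 9 of 10 (median -0.76, 0.0267; adjusted p = 0.991 with an estimated correlation). Lists of other tissue lay higher in 3x, with medians of 1.01 for skeletal muscle (0.0446), 0.42 for endothelial genes (0.0285), 0.41 for epidermal differentiation (0.0457) and 0.29 for adipocytes (0.0312). Erythrocyte genes had a median of 0.54 and were not called (0.0523). With an estimated correlation each adjusted p was 0.991. The first 4 calls were all lost without 2x replicate 1 (0.886, 0.956, 0.0803 and 0.0525) or 3x replicate 3 (0.456, 0.18, 0.119 and 0.732). Without 2x replicate 2 those for muscle (0.802), endothelial genes (0.21) and adipocytes (0.589) were lost. The epidermal call was lost without 2x replicate 3 (0.954) or 3x replicate 1 (0.725), and the endothelial one without 3x replicate 2 (0.229). The muscle median ran from 0.11 to 2.12 on leaving out 1 library.

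limma and voom called 0 genes between 3x and 2x, with 878 at an unadjusted p under 0.05. Camera called 5 lists higher and 7 lower, and 0 with an estimated correlation. The neutrophil-recruiting call was lost without 2x replicate 2 (adjusted p = 0.649), 2x replicate 3 (0.161) or 3x replicate 3 (0.119), and the monocyte chemokine call without 2x replicate 2 (0.422), 2x replicate 3 (0.161) or 3x replicate 3 (0.675). In the order 2x replicate 1, 2x replicate 2 and 3x replicate 3 left out, the medians were -0.42, -0.62 and -0.37 for the cell cycle, -2.72, -0.60 and -0.79 for neutrophil-recruiting cytokines and -1.51, -0.37 and -0.09 for monocyte chemokines, which stood at -1.24 and -1.17 without 3x replicates 1 and 2. Of 47 lists, 1 was called without 3x replicate 3 and 5 without 2x replicate 2.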

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

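The tests on the genes lower after repeat exposure and the title series, on 3x replicate 3, and on Oxtr and Pgr were chosen after the results were seen. The saliva immune library, a single bitten sample outside every comparison, is listed here because 17 of its 47 gene lists lay above naive skin and above first exposure by more than nearly all of 10000 random lists of like expression, with a list mean above both naive libraries. Being 1 library, it gives no test. The random lists held genes drawn independently, while the estimated correlation between genes of a list had a median of 0.507. Correlated genes reach such extremes more readily, so these ranks do not measure chance. Against first exposure the sebaceous gland and circadian clock lists also stood above 100% and 99.9% of the random lists.

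As the median log2 difference from naive skin, the eosinophil list stood at 2.35, the type 2 response at 1.14, keratinocyte activation at 1.12, monocyte chemokines at 0.97, basophils at 0.95, T cells at 0.90, alternatively activated macrophages at 0.89, dendritic cells at 0.82, neutrophil-recruiting cytokines at 0.77, macrophages at 0.74, histamine and prostanoid genes at 0.64, regulatory T cells at 0.62, neutrophils at 0.56, epidermal differentiation at 0.52, MHC class II at 0.51, and coagulation and wound matrix genes at 0.43 each. Of the immune lists outside these 17, gamma delta T cells stood at 0.69, NK cells at 0.51, antimicrobial peptides at 0.42 and mast cells at 0.35, while others lay nearer naive skin, with differences of 0.19 for MHC class I, 0.17 for Langerhans cells, 0.10 for the type 17 and 0.07 for the type 1 response, 0.04 for B and plasma cells, -0.05 for complement and -0.13 for the type I interferon response. Immediate early genes differed by -2 from naive skin but by 0.07 from first exposure, of the same title series, so that their difference from naive skin cannot be told apart from title series. Lists of tissue composition moved in the same library, with differences from naive skin of -3.78 for the hair follicle, -1.83 for melanocytes and -0.83 for adipocytes. The hair follicle mean of 0.68 lay near the 0.85 of naive replicate 2, so that its difference rests on naive replicate 1 (7.55), as does much of that of the melanocyte mean (1.04 against 1.55 in naive replicate 2 and 3.95 in naive replicate 1). From first exposure, the planned reference, the differences were 2.65 for the eosinophil list, 1.38 for the type 2 response, 1.21 for basophils and 2.05 for alternatively activated macrophages. Across genes the library correlated best with first exposure replicate 3 (0.983), which also holds little hair follicle, and several list means lay close to that replicate (macrophages 5.99 against 5.94, MHC class II 5.8 against 5.61, epidermal differentiation 7.85 against 7.99), so that the differences from first exposure in these lists rest mostly on the 2 libraries with much hair follicle, while the eosinophil list stood at 3.92 against 1.94. Its eosinophil list mean of 3.92 and type 2 mean of 4.97 lay above every other library, the highest of which were at 2.4 and 4.81.

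The first pattern weighed was the 42 genes higher and 98 lower after repeat than after first exposure. Of 84 splits of these 9 libraries, 3, the real one included, gave at least 140 genes, a share that would exclude chance if the libraries were exchangeable, but the highest other split gave 4845, with first exposure replicates 1 and 2 and 2x replicate 1 on 1 side, which points to a structure of the samples (those 3 hold the highest hair follicle means), and 0 genes were called without first exposure replicate 2, 2x replicate 3, 3x replicate 1 or 3x replicate 2, so chance is not taken as excluded. A difference between the title series is a candidate explanation for the lower genes, since the saliva immune library lay above all 8 libraries of the other series at 93.9% of them against 12.6% of all genes, while for the higher genes 71.4% lay below all 8 against 6.5%, which did not decide. These genes were chosen for their levels in the 2x and 3x libraries, which are among those 8. That choice alone can raise both shares, so the shares of all genes are not what equal series would give. Naive skin, of the other series, lay below all first exposure libraries at 93 of the 98 lower genes (21% of all genes) and above them at 36 of the 42 higher genes (14% of all genes), as a difference between the series or a change after first exposure alone would both give, on genes chosen for their first exposure levels. Reads shared between ribosomal protein genes and pseudogenes were left undecided by 92 intact ribosomal protein genes with a median log2 fold change of -0.26 (quartiles -0.41 and -0.14), and an earlier selection that left out small-subunit genes by mistake had met the bound set for that explanation. Title series and exposure cannot be told apart, and the saliva immune mouse may itself have met tick antigens, but Rnase2a, at 320 CPM in that library and 2.41 CPM after first exposure, differed inside 1 series.

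The second pattern was 3x replicate 3, whose lists for basophils, monocyte chemokines and keratinocyte activation lay 1.74, 2.11 and 2.5 below the mean of the other 3x libraries on the log2 scale. A swap with a naive library was argued against, as both naive basophil means lay at least 1.25 below the other 3x libraries, so no partner was out of place, although across genes the library correlated best with naive replicate 2 (0.976). Lower depth was argued against by an estimated depth of 98% of the shallower other 3x library. Dilution by other tissue was argued against because the basophil list fell by 1.34 more than the epidermal differentiation, barrier lipid and Langerhans lists, while keratinocyte activation, not part of that test, fell by more than the basophil list, and the muscle list was higher by 2.35. A wrong label from outside these groups and a biopsy taken away from the bite stay open and were not tested, and no biological explanation was tested.

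The third pattern was the high level in unbitten skin of Oxtr, called against the bitten groups together, and of Pgr, called against 2x. Mammary tissue in the naive biopsies was tested with 15 mammary epithelial genes, all at 1 CPM or more in a naive library. They differed between naive replicates 1 and 2 by a median ratio of 19.2, with Krt8 at 48.6 and 2.96 CPM and Csn2 at 46.3 and 2.32 CPM. The ratio of Oxtr was 0.815, which is 23.6 times smaller, and that of Pgr 1.69. However, the mammary genes did not move together: Areg (32.1 and 33.6 CPM, ratio 0.955) and Prlr (104 and 58.2 CPM, ratio 1.79) lay near Oxtr and Pgr. Their median therefore does not say how Oxtr or Pgr of mammary tissue would differ, and the test cannot exclude such tissue. The levels of Krt8 and Csn2 also show that 1 naive biopsy held far more of some mammary transcripts than the other. A larger share of fat was argued against because the adipocyte list, with a median log2 fold change of -0.7 (quartiles -1 and -0.41) in bitten skin, lay far from the -3.26 of Oxtr. Mammary tissue, the bite itself and the hormonal state of the mice stay open, the last of these untested.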

How the results depend on the processing

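The hair follicle covariate and voom were chosen after the data were seen; the other alternatives were planned. The planned edgeR and DESeq2 tests were not run because whole reads could not be recovered for every value. Over the named genes and lists, 3360 alternatives were run: 2789 kept direction and side of the threshold, 512 lost a call (92 under the estimated correlation, 296 without 1 library, 124 otherwise), 45 gained a call and 14 reversed. For every value below that moved, the cause was not tested, unless fewer genes or libraries were in the test. When 1 naive library is left, it is assumed to vary like the other groups.

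Counts of called genes are given in the order first exposure against naive (2 as reported), 2x against naive (6), 3x against naive (1), any bite against naive (7), and repeat against first exposure (140), and in settings not mentioned the count, though not always the genes, stayed within 1.5 times: only the groups compared gave 2 for first exposure, 1 of them among the reported (Rps12 was lost), and no filter gave 9 for any bite, 6 of them among the reported. With log2(CPM + 0.5) the counts were 9 for first exposure and 3 for any bite. With log2(CPM + 0.1) they were 9, 3 for any bite and 50 for repeat exposure. Without a filter they were 9, 11, 5 for 3x and 259 for repeat exposure. At 5 CPM they were 8, 3, 3 for any bite and 7 for repeat exposure. Median-of-ratios scaling gave 90 for repeat exposure and totals without the top 50 genes gave 93. Quantile normalization gave 3 for 2x, 2 for 3x, 1 for any bite and 31 for repeat exposure. Only the groups compared gave 0 for 2x, 0 for 3x and 81 for repeat exposure. Robust moderation gave 9 for first exposure. A minimum log2 fold change of 1 gave 86 for repeat exposure. The hair follicle covariate gave 3 for any bite and 63 for repeat exposure, and 7 called lists in place of 12 between 3x and 2x. voom gave 4 for first exposure, 0 for 3x and 75 for repeat exposure. Array weights, whose estimation did not converge, gave 1753, 34, 276, 427, 583 (2x against first exposure), 5078 (3x against first exposure) and 10299.

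Leaving out 1 library gave 0 to 600 genes for first exposure, 0 to 5 for 2x, 0 to 0 for 3x, 0 to 8 for any bite, 0 to 137 for 2x against first exposure, 0 to 1372 for 3x against first exposure, 0 to 1 for 3x against 2x and 0 to 2260 for repeat exposure. Called lists numbered 14 to 33, 10 to 21, 9 to 15, 8 to 17, 31 to 38, 32 to 39, 1 to 17 and 33 to 39 in the same order, and 0 in every comparison with an estimated correlation. Directions reversed for Cd207 in any bite without naive replicate 2 (0.12, range from -0.71), Krt6a in repeat exposure without first exposure replicate 3 (-0.01, range to 1.28), the hair follicle list with the hair follicle covariate, which is made of that list (-0.11 in first exposure, 0.07 in 2x, 0.03 in 3x and 0.03 in repeat exposure against first exposure), and without naive replicate 2 in first exposure (-1.1, range to 6.25), and, between 3x and 2x, the wound matrix list without 3x replicate 3 (0.23, range from -0.47), the muscle (0.11, range to 2.12) and adipocyte (0.04, range to 0.48) lists without 3x replicate 3, where camera's direction turned and the median did not, the endothelial list (-0.08, range to 0.92) and Mmp9 (-0.04, range to 1.95) without 2x replicate 1, and Il1f9 without 2x replicate 1 (-0.12, range to 0.74) or 3x replicate 1 (-0.10).

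In the saliva immune library, log2(CPM + 0.1) moved the differences from naive skin to 0.88 (dendritic), 0.53 (MHC class II), 1.27 (T cell), 1.22 (type 2), 0.96 (regulatory T cell), 1.12 (basophil), 3.35 (eosinophil) and 1.42 (keratinocyte activation), and those from first exposure to 1.76 (neutrophil), 3.3 (neutrophil-recruiting), 1.61 (T cell), 1.59 (regulatory T cell) and 3.45 (eosinophil). Median-of-ratios scaling moved those from naive to 0.74 (dendritic), 0.43 (MHC class II), 1.08 (type 2), 0.34 (coagulation) and 0.56 (histamine and prostanoid). On simulated data, a change of 1 on the log2 scale was called in 19.4% to 47.8% of genes and a change of 4 in 90.9% to 98.5%, so a change of 1 was missed in most genes. A shift of 1 put into the basophil list was called in all 8 comparisons with the preset correlation, but not for 2x (adjusted p = 0.482) or 3x (0.1) against naive with an estimated one. The simulated genes varied independently, unlike those of the data, so this check cannot support the calls made with the preset correlation.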

Other observations

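The leading genes of the saliva immune library and the counts over splits of 3 against 3 libraries are given here. The genes were picked after their values were seen. Duox2, an oxidase of epithelia, was at 99.6 CPM against at most 19.1 CPM in any other library, and its partner Duoxa2 at 21 against 3.74 CPM. Alox15, a lipoxygenase of eosinophils and macrophages, was at 64.6 against 12.6 CPM, Retnla, a product of alternatively activated macrophages, at 828 against 308 CPM, and the eosinophil genes Siglecf and Ccr3 at 11.5 against 2.62 CPM and 17.7 against 5.98 CPM. Mrgprg was at 129 against 30.4 CPM, and the collagens Col6a5 and Col6a6 were at 329 against 69.9 CPM and 101 against 22.3 CPM. Il13 was at 3.94 CPM and Il4 at 2.07 CPM in this library.

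With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count was 0 in all 3 comparisons, so the number of splits that give as many decides nothing. The highest other split gave 3215 genes for 2x against first exposure, with first exposure replicates 1 and 2 and 2x replicate 1 on 1 side, which points to a structure of the samples, 0 for 3x against first exposure and 6 for 3x against 2x.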
